A study of Mus musculus with 2 samples.

How the data were processed

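The series compares 1 control library with 1 library labelled Utx cKO, each from the cortex of an embryo at embryonic day 14.5. Per the labels' protocols, RNA was extracted with Trizol, treated with DNase I, selected with oligo(dT) beads and made into a TruSeq library from 1 ug of total RNA. The submitters' processing notes name TopHat2 2.0.12, Bowtie 1.0.1 and the mouse build GRCm38.p6. The counting tool, the annotation, the strand setting and the treatment of reads that match several genes are not given in the sources used here, so genes with near-identical copies or overlapping partners are uncertain.

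The deposited table holds 15657 genes with a count per library. The values are multiples of 0.5, so the authors' counts are treated as estimated counts, and 9350 genes have a fractional count in either library. The smallest CPM of a gene in its higher library was 1.00, and the smallest count summed over both libraries was 34, so genes below about 1 CPM in both libraries have no row in the table used here. Among marker genes, Xist, Tsix, Sox2 and Tubb3 had no row and were not analysed here. The authors also deposited RPKM values. From counts and RPKM of 14428 genes with at least 50 control counts, the length behind the authors' RPKM matched the whole gene span with introns within 5% for 73.2% of genes, and the exon length for 3.98%. The table further gives, per the file headers, the authors' log2 fold change, log2 CPM, p-value and adjusted p-value. How the spread behind the authors' p-values was set with 1 library per group is not given in the sources used here.

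Counts were rounded to whole numbers for the scaling and the intervals, and scaled with TMM factors from edgeR 4.0.16 in R 4.3.3, which were 1.08 for the control-labelled and 0.929 for the cKO-labelled library. Ratios are cKO-labelled over control-labelled with 0.5 counts added per library, scaled to library size. Intervals are exact Clopper-Pearson 95% intervals on the share of a gene's counts in each library. Reads amplified by PCR are not independent molecules, so intervals and limits cover counting error only. A fold against a count of 0 was computed against 3 counts in that library. No test across libraries was possible. A gene counted as higher or lower when it had at least 20 counts summed, a ratio of at least 1.5 or at most its inverse, and an interval that left out 1. The floor of 20 removed 0 genes. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used, and figures were drawn with matplotlib 3.10.9.

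The rule was tested on simulated data for this comparison, with 200 of 15657 genes changed and counting error as the only noise. It recovered 48% of genes changed 1.5-fold, 100% at 2-fold, 98% at 3-fold and 100% at 4-fold, 50 genes each, and called 0.628% of the 15457 unchanged genes. Variation between embryos is not in this simulation.

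Before the data were examined, 40 gene lists were fixed, 38 by name and the ribosomal protein and mitochondrially encoded families by symbol. As run, the symbol filter for the ribosomal protein family also dropped every Rps gene, so that list holds Rpl genes only. For each list the median log2 ratio was placed among 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these libraries. Another 3 lists were added once the data had been seen. Named genes are Kdm6a, Kdm6b, Uty and Pten, the 12 most extreme genes in each direction ranked by the interval bound nearest to no change, and up to 4 members of each list with the largest absolute log2 ratio. Predicted, clone-named, pseudogene and small RNA gene names were passed over, 3 among the higher and 2 among the lower genes. Genes outside the rule were named after their values were seen. These are Ddx3x, Nes, Pax6, Eomes, Axin2, Rspo2, Lmx1a, Ttr, Malat1, Neat1, Lars2, Gm26924, Hist1h2ap and mt-Rnr2. Also among them are Lhx2, Emx2, Fezf2, Tbr1, Neurod6, Hba-x, Hbb-y, and members of the 3 added lists such as Kdm5c and Eif2s3x.

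Gene positions and spans are from the GENCODE mouse release M21 annotation on GRCm38, the build in the labels, and 15527 of the gene identifiers matched it. The background density is the median control count per kb of gene span over 217 genes of at least 100 kb with under 0.1 counts per kb in the cKO-labelled library. Alternatives planned beforehand were total-count scaling, DESeq2 1.42.0 size factors, no floor, a floor of 100 counts, a pseudocount of 2, a 2-fold rule, the authors' RPKM in place of counts, leaving out haemoglobin, mitochondrial and ribosomal RNA genes, 50 expression bins, list members with any count, and other thresholds on the authors' calls. Subtracting the background, keeping genes at 5 or more times its density and matching lists on gene span were added after seeing the data.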

Results

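RNA was sequenced from mouse cerebral cortex at embryonic day 14.5, when progenitors lining the ventricle are producing cortical neurons. The series holds 1 control library and 1 library labelled as a conditional knockout of Utx (gene symbol Kdm6a), an X-linked histone demethylase that removes methyl groups from lysine 27 of histone H3. The knockout label gives floxed alleles on both X chromosomes together with a Cre transgene, and both embryos are labelled female on a C57BL/6 background. Counts over 15657 genes summed to 33112816.5 in the control-labelled library and 30363547.5 in the cKO-labelled library. With 1 library per group there is no replicate error, so each difference below is a difference between these 2 libraries and carries no p-value. Intervals in brackets are 95% intervals for counting error only, and folds are after TMM scaling. A fold against a count of 0 takes 3 counts in that library.

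The first comparison asks whether the knocked-out gene and sex-linked genes follow the labels. Kdm6a (ENSMUSG00000037369, GRCm38 chromosome X, 18162575 to 18279936, plus strand) had 1373 counts in the control-labelled library and 909 in the cKO-labelled library, a ratio of 0.836 (0.768 to 0.910). This is the total over the gene, so it does not show whether the floxed exons were removed. Uty, the Y-linked relative of Kdm6a (chromosome Y, 1096861 to 1245759, minus strand), had 13 and 1961.5 counts, a 183-fold difference (111 to 359). Eif2s3y, a translation initiation factor subunit (chromosome Y, 1010543 to 1028847), had 2 and 2530 counts, a ratio of 1250 (442 to 13203). For the RNA helicase gene Ddx3y (chromosome Y, 1260771 to 1286629) the counts were 2 and 1595, a ratio of 788 (278 to 8326). Kdm5d, a histone H3 lysine 4 demethylase gene (chromosome Y, 897788 to 956786), had 0 and 1379 counts. It was 581-fold higher in the cKO-labelled library against 3 counts, with a lower interval bound of 472. The X-linked relatives of these genes, which are transcribed from both X chromosomes in female mice, had lower ratios, with log2 values of -0.38 for Eif2s3x, -0.35 for Kdm5c and -0.13 for Ddx3x, beside -0.26 for Kdm6a. Y-linked transcripts in this amount contradict the label of a female with floxed alleles on both X chromosomes. The libraries are therefore called by their labels throughout, and no direction given here is a measured effect of Utx loss. Xist was not analysed here.

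**Figure D1:**
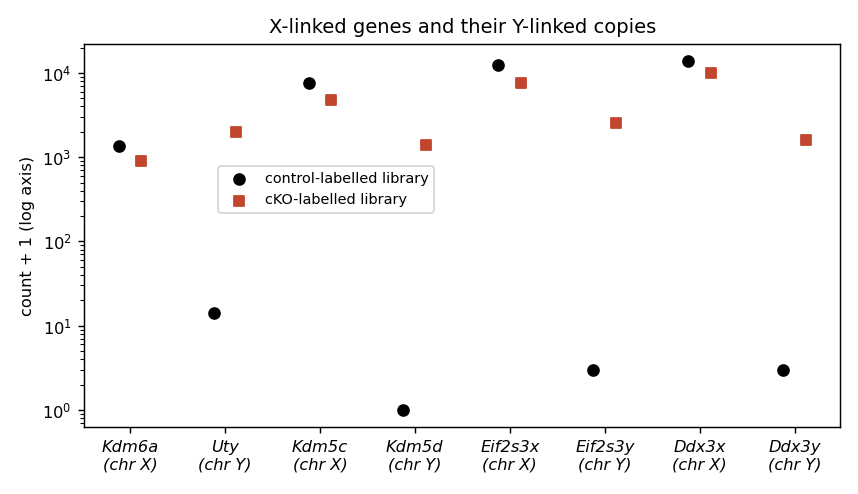
Counts plus 1 on a log axis for 4 X-linked genes and their Y-linked relatives, with 1 point per library (black circles control-labelled, red squares cKO-labelled). The control-labelled library had 0 to 13 counts on the Y-linked genes, and the cKO-labelled library had 1379 to 2530.

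The main comparison asks which genes differ between control and cKO-labelled cortex. Of 15657 genes, 1022 were higher by at least 1.5-fold in the cKO-labelled library, 3109 were lower and 11526 lay between. Most of the lower genes had few counts for their gene span in the control-labelled library. Density here is a gene's total count over its span, so it does not show where in the gene the reads lie. Among 217 genes spanning 100 kb or more with under 0.1 counts per kb in the cKO-labelled library, the median density in the control-labelled library was 0.850 counts per kb of gene span, against 0.0489 in the cKO-labelled library. These genes were picked for low cKO-labelled density and needed about 1 CPM in either library to have a row. The contrast is therefore largely set by that choice, and long genes of lower control density may be missing from it. By the reverse choice, the only gene spanning 100 kb or more with under 0.1 counts per kb in the control-labelled library was the Y-linked Uty. Of the 1255 genes at 1 to 2 times that control density, 79.8% were lower, against 2.64% of the 6215 genes at over 50 times that density. Among the 12085 genes at 5 or more times the density in either library, 698 were higher and 871 were lower when scaled on these genes alone, a restriction chosen after seeing the data. With the main scaling 787 of these genes were lower and more than 787 were higher, so the balance turned with the scaling. Scaling by total counts moved the median log2 ratio of all genes by -0.21 and gave 497 higher and 3824 lower genes, so that 11.5% of the calls were higher in place of 24.7%.

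**Figure D2:**
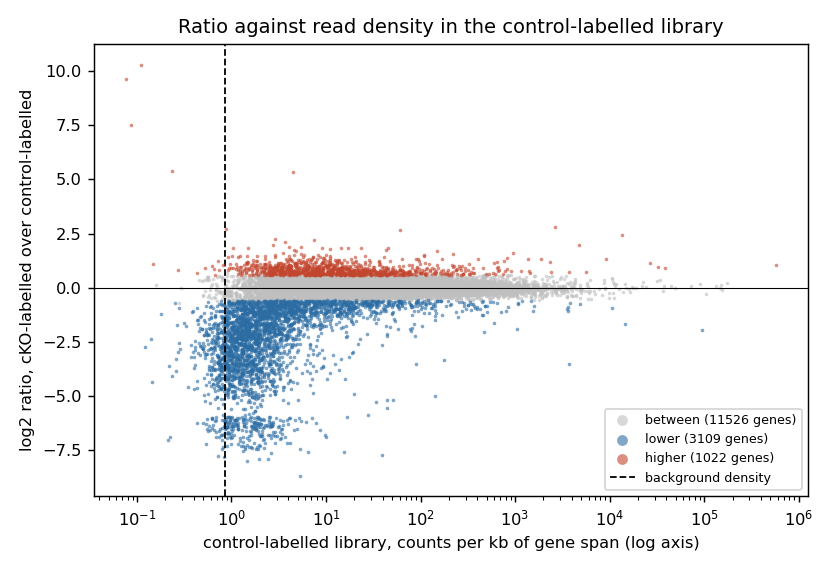
Log2 ratio of the cKO-labelled over the control-labelled library against counts per kb of gene span in the control-labelled library (log axis), with 1 point per gene coloured by the 1.5-fold rule. Lower genes crowd around the dashed background density of 0.850 counts per kb. Genes without a span or with 0 control counts are not drawn.

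Beside the 4 Y-linked genes, the strongest higher genes by the fixed rule included small structural RNAs. Rmrp, the RNA of RNase MRP, was 6.94-fold higher (6.41 to 7.53), Rn7sk, which holds back a transcription elongation factor, 5.36-fold (5.19 to 5.54), and Rpph1, the RNA of RNase P, 3.87-fold (3.66 to 4.11). The protocol selects RNA with oligo(dT) beads, and whether these RNAs passed that step alike in both libraries was not tested. The synaptic adhesion gene Nrxn3 was 3.47-fold higher (3.41 to 3.53). Dnah7b, a dynein heavy chain gene, was 3.56-fold higher, and the complement gene C2 was 3.54-fold higher. Ceacam16 rested on 8 and 43.5 counts. Eif3j2 had 0 and 258 counts, 109-fold higher against 3 counts, with a lower interval bound of 87.7. It has a near-identical copy, Eif3j1, so the assignment of its reads is uncertain. At the other end were genes of the cortical hem, the signalling centre at the medial edge of the cortex. Wnt3a had 224.5 counts in the control-labelled library and 0 in the cKO-labelled library, 59.2-fold lower against 3 counts, with a lower interval bound of 47.9. Rspo1, a secreted activator of Wnt signalling, was 58.8-fold lower (31.3 to 144), and Wnt8b was 38.9-fold lower (23.7 to 73.7). Gmnc and Ccno, which act early in the formation of multiciliated cells, had 201 and 116.5 counts in the control-labelled library, against 1 and 0. The rest of the 12 lower genes were Ofcc1, Ano2, Zan, Cytip, Otogl, Stab2 and Abca12, with 0 to 3 counts in the cKO-labelled library. In the control-labelled library these 7 lay between 0.846 (Stab2) and 2.30 (Cytip) times the background density.

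Neuronal genes were higher in the cKO-labelled library. Of 18 measured pan-neuronal genes 13 were higher and 0 lower, with a median log2 ratio of 0.69, above each of 10000 random lists matched on expression. Nrxn1 was 2.44-fold higher, the synaptic vesicle calcium sensor Syt1 1.95-fold and the glutamate receptor gene Gria2 1.79-fold. Among 28 synapse genes 16 were higher and 0 lower (median 0.64), led by Nrxn3 and by the NMDA receptor gene Grin2b at 2.86-fold. The axon guidance list had 13 of 28 higher (median 0.53), including the Slit receptor Robo2 at 2.52-fold and Plxna4 at 2.43-fold. In the upper-layer list 5 of 11 were higher and 1 was lower (median 0.57), with Pou3f1 at 2.09-fold and Unc5d at 1.96-fold. The lower gene was Inhba at 3.54-fold, on 35 and 7.5 counts. Among deep-layer genes 5 of 12 were higher and 1 was lower (median 0.45). Fezf2 and Tbr1 had log2 ratios of -0.46 and 0.28, and Crym was 2.51-fold lower on 42 and 13 counts. Higher were Foxp2 at 2.46-fold, Bcl11b at 2.11-fold and Sox5 at 2.08-fold. Genes of ventral telencephalon and interneurons moved with them, with 13 of 19 higher (median 0.66), among them the GABA-synthesising enzyme Gad2 at 2.48-fold, the vesicular GABA transporter Slc32a1 at 2.48-fold and Lhx8 at 2.52-fold. The striatal list had 6 of 12 higher and 1 lower (median 0.63), with Ebf1 at 2.77-fold and Tac1 at 2.20-fold, whereas Penk was 2.39-fold lower. The median ratio also increased with gene span, from -0.05 in the shortest 10% of the 12085 denser genes to 0.40 in the longest 10%. With random lists matched on span as well, chosen after seeing the data, the deep-layer list lay at the 70.7th percentile and axon guidance at the 93.4th (98.6th after background subtraction), while the other 5 lists stayed at or above the 99.1st percentile.

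Most progenitor and cell cycle genes did not pass the 1.5-fold rule. In the radial glia list 3 of 20 were higher and 1 was lower (median 0.00), and the radial glial intermediate filament gene Nes and the transcription factor gene Pax6 had log2 ratios of 0.00 and -0.10. Slc1a3 was 1.70-fold higher, whereas Hes1, an effector of Notch signalling, was 1.58-fold lower. Lhx2 and Emx2 had log2 ratios of -0.54 and -0.40 without passing the rule. Of 13 intermediate progenitor genes 0 were higher and 1 was lower, the proneural gene Neurog1 at 1.76-fold. Their median of -0.11 lay at the 0.245th percentile, and at the 4.03rd when also matched on span. Log2 ratios were 0.50 for Insm1, 0.10 for Eomes and -0.36 for Neurog2. The G2/M list had 0 of 23 past the rule (median -0.13) and the G1/S list 1 higher and 1 lower of 22 (median -0.13), with Cdk6 at 1.78-fold higher and Ccne1 lower with a log2 ratio of -0.59. Small as they were, both cell cycle medians lay at or below the 0.01th percentile of random lists. Pcna, of the G1/S list, had a log2 ratio of -0.50 without passing the rule. The cell cycle inhibitor list had 1 higher and 2 lower of 11, with Cdkn1a at 1.86-fold lower.

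Genes of the medial edge of the cortex, its coverings and its vessels were lower in the cKO-labelled library. Of 19 hem and choroid plexus genes 18 were lower and 0 higher, with a median log2 ratio of -3.30, below each of 10000 random lists. Beyond Wnt3a, Rspo1 and Wnt8b these included Clic6 (21.8-fold), and, named for this description, Rspo2 (18.4-fold), Lmx1a (10.8-fold) and the choroid plexus transport protein gene Ttr (9.82-fold, 129 and 10 counts). The pericyte and meninges list had 12 of 18 lower (median -1.08), such as the forebrain stromal factor Foxd1 at 6.24-fold and the proteoglycan gene Dcn at 4.20-fold. Extracellular matrix genes had 10 of 19 lower (median -0.59), including Col6a2 at 3.16-fold and Col5a2 at 2.43-fold. For erythroid genes the count was 9 of 15 lower (median -0.65), with Hemgn at 4.33-fold on 67.5 and 12 counts. Of the globin genes Hba-x was 1.90-fold lower. Hbb-y, with 53929 and 38675.5 counts, was 1.10-fold lower and did not pass the rule. The endothelial list had 5 of 14 lower (median -0.49), with the vascular cadherin Cdh5 at 1.84-fold. In the microglial list 6 of 13 were lower (median -0.40), with Aif1 at 11.3-fold, but random lists of such low expression had about the same median (52.3rd percentile). In the diencephalon to hindbrain list 6 of 11 were lower (median -3.13), and in the muscle and cartilage list 6 of 9 (median -2.37). Some of these lower genes had a low density, such as Pax7 at 0.476 and Ttn at 0.815 times the background density. Others were denser, such as Phox2a at 9.33 and Des at 5.70 times. After background subtraction the medians of these lists were -0.55 and -0.38. The first list, at the 0.4th percentile before, then lay at the 10.7th when also matched on span. The only Hox gene measured, Hoxd3, was 4.21-fold lower at 1.26 times that density. Of the Cajal-Retzius genes 3 of 10 were lower (median -0.09), including Trp73 at 1.63-fold, and of the glial genes 3 of 10 (median 0.04), including Pdgfra at 2.16-fold.

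**Figure D3:**
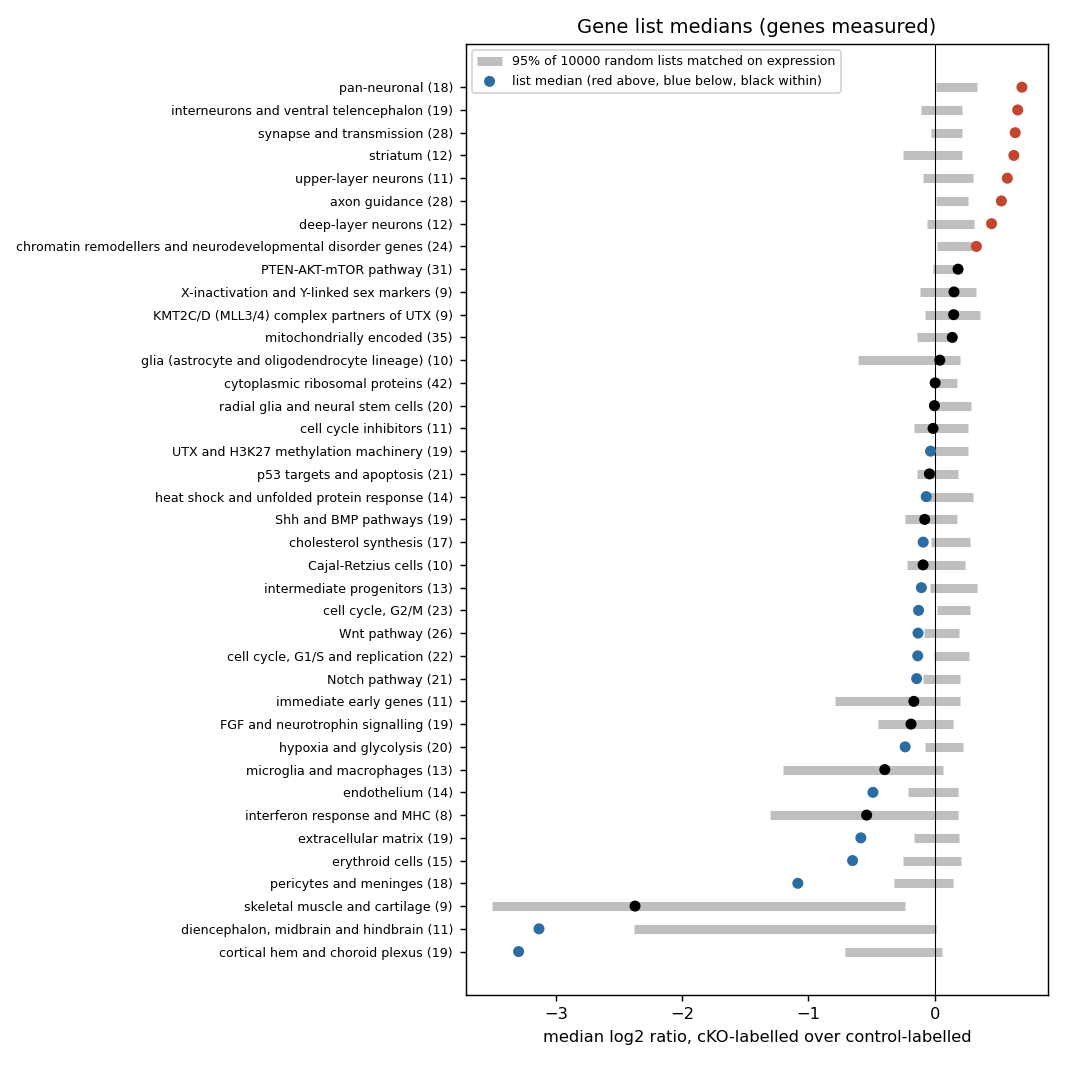
Median log2 ratio of each gene list fixed before the data were examined and with at least 5 measured genes (points; the number measured is in brackets), and the range holding 95% of 10000 random lists matched on expression (grey bars). The pan-neuronal median of 0.69 is the highest, and the hem and choroid plexus median of -3.30 is the lowest. The ribosomal protein list holds Rpl genes only.

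Partners of the study's gene and the PTEN pathway were examined next. In the list of H3K27 methylation regulators 1 of 19 was higher, Uty, and 1 was lower, the Polycomb protein gene Cbx7 at 1.51-fold (median -0.03). The other H3K27 demethylase gene, Kdm6b, had a ratio of 1.32 (1.27 to 1.37). In the list of KMT2C/D complex partners 1 of 9 was higher, Kmt2c at 1.51-fold (median 0.15). Neither Cbx7 nor Kmt2c passed the rule after background subtraction. Pten (chromosome 19, 32757497 to 32826160, plus strand), the phosphatase that restrains AKT signalling, had 4528 and 3882.5 counts, a ratio of 1.08 (1.04 to 1.13), and its log2 ratio of 0.12 became -0.10 under total-count scaling. In the PTEN-AKT-mTOR list 2 of 31 were higher and 2 lower (median 0.18, 92.7th percentile), with Akt3 at 1.76-fold and Igf1r at 1.66-fold higher, and the mTOR inhibitor Deptor at 3.05-fold and Eif4ebp1 at 1.98-fold lower. The list of chromatin remodellers had 3 of 24 higher and 0 lower (median 0.33, 99.2nd percentile, but 96.6th after background subtraction with matching on span), namely Crebbp, Chd8 and Smarca2.

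Among signalling lists, 6 of 26 Wnt pathway genes were lower and 2 higher (median -0.13, 0.26th percentile), including the Wnt target Sp5 at 11.5-fold and Dkk3 at 3.42-fold lower, with Axin2, named for this description, at 1.70-fold lower. In the Notch list 3 of 21 were lower (median -0.14, 0.29th percentile), with Hey2 at 2.13-fold. Of the Shh and BMP genes 7 of 19 were lower and 2 higher (median -0.08, and 0.08 after background subtraction), among them the BMP target Id3 at 4.06-fold lower (3.50 to 4.75). The FGF list had 6 lower and 4 higher of 19 (median -0.19) but 3 lower and 6 higher after background subtraction (median 0.30), with the receptor gene Fgfr3 at 2.09-fold lower from 12324 counts and Etv1 at 2.01-fold higher. Hypoxia and glycolysis genes had a median of -0.23, below each random list, with 4 of 20 lower and 2 higher, and lactate dehydrogenase Ldha was 1.77-fold lower. Heat shock genes had 2 of 14 lower (median -0.07, 1.92nd percentile, but 23.4th when also matched on span), led by Hspa8 at 2.07-fold, and cholesterol synthesis genes 0 of 17 past the rule (median -0.09, 0.14th percentile). Interferon and MHC genes had 4 of 8 lower (median -0.54, 23.7th percentile), with H2-K1 at 2.02-fold, p53 and apoptosis genes 5 of 21 lower (median -0.04) and immediate early genes 4 lower and 1 higher of 11 (median -0.17). The ribosomal protein list, which as run held Rpl genes only, had 2 higher and 1 lower of 42 (median 0.00). Mitochondrially encoded genes had 9 higher and 1 lower of 35 (median 0.14, 96.2nd percentile). The X and Y marker list had 4 of 9 higher, all Y-linked. Under total-count scaling the medians of the mitochondrial, PTEN-AKT-mTOR, KMT2C/D, glial, ribosomal and X and Y lists turned negative.

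The authors' deposited table makes its own comparison of the same libraries. It calls 1331 genes at an adjusted p under 0.05, 1318 of them lower and 13 higher in the cKO-labelled library. All 13 and all 1318 also passed the 1.5-fold rule in the same direction. In the authors' deposited table the genes called lower had a median of 70 counts in the control-labelled library and 4 in the cKO-labelled library, and 248 were at 0 in the latter. The authors' deposited table gives Kdm6a and Pten adjusted p-values of 1. These p-values compare 2 libraries, not 2 genotypes.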

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

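No paired analysis was possible because each group holds 1 library, and leaving out a replicate could not be run for the same reason. The count floor removed no gene, so running without it tested nothing. Background subtraction, the density restriction and span matching were chosen after seeing the data. The log2 ratio of Kdm6a was -0.26 and kept its sign in each of 6 alternatives, reaching -0.47 with total counts and -0.47 with RPKM. The 1022 higher genes became 497 with total counts, 502 with RPKM, 237 at 2-fold and 1829 after background subtraction, 929 of them shared with the main set. The 3109 lower genes became 1725 with the floor of 100 counts and scaling on the genes left (1657 shared), and 1923 after subtraction (1865 shared). Among genes at 5 times the background density, scaled on these genes alone, 871 were lower (787 shared). The DESeq2 factors, the pseudocount of 2 and leaving out abundant RNAs kept both counts within 1.5 times. In the authors' deposited table the 13 genes called higher became 20 at p under 0.01 and 7 with a 2-fold stricter fold, and the 1318 called lower became 89 at 5 times the background density. After background subtraction 869 of the genes that the authors called lower still passed the 1.5-fold rule as lower. Total-count scaling shifts every ratio alike, and the cause of the other changes was not tested except by the construction of the stricter rules.

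Of the named genes that passed the 1.5-fold rule, 7 changed sign after subtraction, because little or nothing was left of their control counts, namely Ofcc1 (1.67), Fgf10 (3.28), Pax7 (2.43), Aldh1a2 (0.31), Ttn (5.85), Fas (0.0821) and Hoxd3 (0.0579). Otogl and Stab2, with 0 counts in the cKO-labelled library, moved to a log2 ratio of 0. With span matching, 5 of 40 lists lost a position outside the range of 95% of random lists, namely H3K27 methylation (5.24th percentile), intermediate progenitors (4.03rd), deep-layer neurons (70.7th), heat shock (23.4th) and axon guidance (93.4th), and interferon (0.84th) and mitochondrially encoded genes (98.8th) gained one, and 50 bins changed none.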

Other observations

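Each explanation test in this part was chosen after the result had been seen. Further genes differed between the libraries. In a list of small structural RNAs added once the data had been seen, which holds the RNA polymerase III transcripts Rmrp, Rn7sk and Rpph1, 5 of 6 were higher in the cKO-labelled library (median log2 ratio 1.90), Terc being the exception. The first 3 were already among the 12 strongest higher genes, so this describes the list and does not test it. Among single genes named after their values were seen, the nuclear RNA Malat1 was 2.51-fold higher and the mitochondrial ribosomal RNA genes mt-Rnr1 2.18-fold and mt-Rnr2 1.89-fold higher. Gm26924, the gene with the most counts and grouped here with the ribosomal RNA genes, took 3.15% of the control-labelled and 5.59% of the cKO-labelled library. Whether ribosomal RNAs passed the oligo(dT) selection alike in both libraries was not tested. Lars2 was 3.04-fold higher. Neat1, another nuclear RNA, was 1.36-fold lower. The histone gene Hist1h2ap was 3.92-fold lower from 46155 counts, and the nucleosome assembly genes of the authors' annotation had a median of 0.19 with 15 higher and 1 lower of 57. In a list of multiciliated cell genes, likewise added later, 10 of 12 were lower and 1 higher (median -1.88), including Mcidas at 18.5-fold lower. After background subtraction 8 were lower and 3 higher (median -0.81).

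A scan of 857 biological process terms in the authors' annotation, on genes at 5 times the background density and against random lists matched on expression and span, placed 10 terms in the top 0.1% and 30 in the bottom 0.1%, where 0.857 would lie each way if terms were independent random lists. Neurotransmitter secretion (median 0.53, 10 higher and 0 lower of 23) and axonogenesis (median 0.33, 15 higher and 1 lower of 63) stood at the top. Collagen fibril organization (median -0.33, 9 lower and 2 higher of 23) and angiogenesis (median -0.06, 27 lower and 10 higher of 146) stood at the bottom.

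Y-linked transcripts in the library labelled female were weighed first. Reads of X-linked relatives counted on Y-linked genes are argued against, because the control-labelled library had only 4 counts on Eif2s3y, Kdm5d and Ddx3y together beside 33589 on their X-linked relatives, while the cKO-labelled library had 5504 beside 22143. Male tissue in the cKO-labelled library predicts lower X-linked genes that escape inactivation, and the median of 5 such genes, -0.34, lay at the 0.17th percentile of matched X-linked lists. The candidate explanation is therefore a male embryo, or some male tissue, under the cKO label, and the Kdm6a log2 ratio of -0.26 lies within the -0.38 to -0.13 of those escape genes. A swap between the 2 libraries would not resolve this, since both are labelled female, and whether Kdm6a was deleted stays untested.

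The authors' genes called lower were weighed in 2 parts among the 1310 with a known span, of which 1221 had under 5 times the background density in the control-labelled library and 89 had more. Left without the long genes that set the background, 60.1% of 1012 in the first part lay within 2-fold of it. Among 1378 uncalled genes of like count, also under 5 times, the share was 39.4%. Reads spread evenly over gene bodies, as residual genomic DNA would give, may account for some of the first part, but these shares do not decide it. Of 32 genes from receptor and other families foreign to cortex, 31 were denser in the control-labelled library (medians 1.37 and 0.0455 counts per kb). Control counts of the genes called lower rose with span (Spearman rho 0.66), against 0.37 among genes at 5 or more times the density. Both go with an even background but cannot decide it, as a row needs about 1 CPM in either library. The totals differ 1.09-fold, far below the median fold of the first part, 15.9 in raw counts. The authors' calls were chosen for a large difference, so this comparison could not have come out otherwise and does not test depth. For the 89, which subtraction cannot test because they were chosen for their density, background stays open too. Of the 217 long silent genes 0 reached 5 times the density. Among the same 32 genes foreign to cortex 21.9% did, against 6.79% of the authors' calls. These shares cannot decide it, because the 217 genes set the background themselves. A short gene also needs a high density to reach the 1 CPM that gives it a row.

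The third pattern is higher neuronal lists beside lower hem, meningeal, vascular, erythroid and matrix lists. Gene length is argued against as the whole cause for the upper-layer, pan-neuronal, interneuron, striatal and synapse lists. Their lowest span-matched percentile, with or without background subtraction, was 98.7. The matching used 10 span bins per expression bin. The longest 10% of the denser genes ran from 112 to 2271 kb, so the longest members were matched only loosely. Length may account for the deep-layer list, at most at the 71.3rd percentile. It stays open for axon guidance, at the 93.4th without subtraction and the 98.6th with it. An even background is argued against for these lower lists, since 5 of 5 stayed under the 2.5th percentile after subtraction, unlike the low diencephalon to hindbrain list, which moved to the 10.7th, though an uneven background was not tested. More ventral and less medial tissue in the cKO-labelled dissection remains possible. Its test compared the ventral list with the pan-neuronal list, from which it differed by only -0.0335. That test cannot decide it, because ventral neurons also express pan-neuronal genes. Genes of dorsal cortex went both ways, with log2 ratios of -0.40 for Emx2 and -0.46 for Fezf2 but 0.28 for Tbr1 and 0.53 for Neurod6. With 1 library per group, any differences in genotype, sex of the embryo, dissection or library preparation could not be separated, and an effect of Utx loss is among the open explanations.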
